A study of Homo sapiens with 12 samples.

How the data were processed

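The series measured RNA and N6-methyladenosine (m6A) marked RNA in Kasumi-1, a human acute myeloid leukaemia cell line. Per the labels, the cells carried a lentiviral short hairpin RNA (shRNA) against WTAP or a scrambled control, and selection with puromycin at 2 µg/ml began 48 h later and lasted at least 24 h. Poly(A) RNA was purified, fragmented and partly taken through an anti-m6A antibody (methylated RNA immunoprecipitation, IP), with input RNA kept beside it, per the labels' protocols. The libraries were made with dUTP in the second strand, which marks strand, per the labels. The 12 libraries fell into 4 groups of 3, control input, shWTAP input, control IP and shWTAP IP, and the labels call the 3 of a group biological replicates. Groups and replicate numbers were taken from the sample titles.

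The expression table held FPKM values (fragment values scaled by the authors to transcript length and library total) for 27411 genes in the 6 input libraries, as the authors deposited them. The program that made them, the genome build, the annotation and whether fragments were counted by strand are not given in the sources used here. The submitters' processing notes name fastp, HISAT2, HOMER and ChIPseeker, with no version and no role. FPKM is scaled to each library's total, so a shift of all RNA alike cannot be seen, and a gain in abundant genes lowers the others. The depth of each library is unknown, since FPKM sums (177800 to 187200) carry no depth, and no counting interval was set on a gene's value. Symbols in the table were compared with the RefSeq gene table given for human: 20187 matched, and 99.9% of these overlapped the RefSeq gene of that symbol.

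The peak lists were 1 for control and 1 for shWTAP, each setting IP against input, per the file headers. The fold enrichment, a ratio of IP over input for each peak, was computed by the authors and is used here only to describe and rank peaks within a list. The p-value of each peak came with the deposited lists and reached at most 0.05. Its log10, and the log10 of a false discovery rate, were deposited as scores and were used to rank and filter peaks. The peak caller, and whether the 3 replicates were pooled before calling, are not given in the sources used here. With 1 list per condition there is no replicate of a peak and no test between the lists. Each peak came with an assigned gene and an annotation of 5' UTR, exon or 3' UTR. IP values per gene and library were not analysed here, so the intended test of IP over input was not run. A loss or gain of m6A at a site was therefore not measured, only whether a peak was listed.

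Expression was tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) on log2(FPKM + 1), shWTAP minus control, over the 6 input libraries with no covariate. A gene was kept when its FPKM was at least 1 in at least 3 libraries, which left 11383 genes, and a call needed a Benjamini-Hochberg adjusted p under 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Fold values printed beside 2 group means are ratios of mean FPKM. With 3 against 3 libraries the exact 2-sided permutation test of 1 gene cannot go below p = 0.1, so calls rest on limma's model. The 29 gene lists were tested with camera (preset inter-gene correlation 0.01) where at least 5 members were measured, which was so for 22, with adjustment over those 22. Camera asks whether a list moved relative to all other tested genes. It was run again with an estimated correlation, and fry was run beside it, whose p asks whether the genes of a list move 1 way on balance and whose mixed p asks whether they change in either direction. Neither fry value compares a list with other genes.

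Peaks were compared with bedtools 2.31.1 on their exonic blocks, and an overlap of at least 1 bp counted. The plan asked for the same strand where strand is given. The lists give only the strand of the assigned gene, which can differ between the lists for the same interval, so strand was ignored and the same-strand value is an added alternative. Genes were classed by whether a peak assigned to them stood in both lists, in 1 or in neither, and camera compared the classes in the input fit. Intervals of the share of overlapped peaks are 95% Wilson intervals and cover counting error only.

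The gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The rule named WTAP, KDM4B, HIF1A, MYC, METTL3 and METTL14. It added the 10 largest rises and 10 largest falls among called genes with a symbol, a mean FPKM of at least 5 in the higher group and no overlap between the groups. From each list it took up to 4 measured members with the smallest adjusted p, and from the peaks those of the genes always named and the 5 highest enrichments with and without an overlap in each list. Which of these members stand in the text was chosen after their values were seen, mostly those called, and the ranges over alternatives were computed for all of them. The values of 1 called list member are not reported here. Other genes named in the text were chosen after their values were seen. Control 3 and shWTAP 1 carried more mitochondrial mRNA than the other 4 input libraries, a feature found in the data, and they are treated as a possible batch that holds 1 library of each group.

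Alternatives covered the pseudocount, the filter, quantile normalization, median centring, eBayes without trend, a block for the replicate number, leaving out each library in turn, an estimated correlation, stricter peak thresholds and other definitions of overlap. Added after the data were seen were the fit without both libraries of high mitochondrial mRNA, a 2-level block for them, a fit without genes overlapping another listed gene on the same strand, a false discovery rate of 0.05 for peaks, overlap by whole spans and by the strand of the assigned gene, peak classes by interval, and a test of the KEGG pathways that the expression table assigns to genes. For lists and peak classes, a change of direction under an alternative was first read from the sign of the median alone. It is now read from camera's direction, with the median set against that of the other genes, a switch made after the first counts were seen. The fit was tested on simulated data drawn for the 11383 genes with 200 changed. It recovered 67.2% of genes changed by 0.5 on the log2 scale and 98.5% of those changed by 1, and 3.80% of its calls were unchanged genes. The simulated noise was independent between genes and took its spread from the fit itself. It held no batch, and each change was the same in every shWTAP library, so these shares need not hold for the real libraries.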

Results

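The data came from Kasumi-1, a cell line from an acute myeloid leukaemia that carries the t(8;21) translocation. WTAP, a regulatory subunit of the complex that writes m6A on mRNA, was silenced with an shRNA, and cells with a scrambled shRNA were the control. FPKM values were analysed for 6 input libraries, 3 control and 3 shWTAP, and the m6A peaks were analysed as 1 list per condition. The libraries listed between 11216 and 11392 genes at 1 FPKM or more, and their sequencing depth is unknown. At most 7 genes had identical values in any pair of libraries, so no library is a copy of another. Each was counted as a separate replicate because the labels call them biological replicates. Over the tested genes on the log scale, libraries of a group correlated at r = 0.975 to 0.991. shWTAP 1 correlated more with the controls (0.981, 0.982 and 0.986) than with shWTAP 2 (0.975) or shWTAP 3 (0.978). The correlation is across genes, which are not independent replicates. The 13 mitochondrially encoded mRNAs made up 0.634% of all FPKM in control 3 and 0.631% in shWTAP 1, against 0.301% to 0.333% in the other 4 libraries. The first principal component held 49.6% of the variance. shWTAP 1 lay at -4.51 on it, between the controls (-15.2 to -8.49) and the other shWTAP libraries (19.1 and 20.6).

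The first comparison asked whether the targeted mRNA and the genes around it differed in level. WTAP mRNA fell from 11.5 ± 0.234 FPKM (SD, n = 3) in control to 6.38 ± 0.644 FPKM (SD, n = 3) in shWTAP, or 55.6% of the control level. Its log2 change was -0.76 (SE 0.08, limma adjusted p = 0.00663), and each shWTAP library (5.69 to 6.97 FPKM) lay below each control library (11.2 to 11.7 FPKM). METTL3, the catalytic subunit of the m6A writer, stood at 7.50 ± 0.310 and 8.38 ± 0.635 FPKM, and its partner METTL14 at 4.59 ± 0.399 and 5.06 ± 0.738 FPKM, neither past the threshold (limma adjusted p = 0.301 and 0.558). KDM4B, a histone lysine demethylase, was measured at 5.36 ± 0.242 FPKM in control and 5.48 ± 0.866 FPKM in shWTAP, a log2 difference of 0.02 (SE 0.11, limma adjusted p = 0.932). HIF1A, the hypoxia-inducible transcription factor subunit, was at 20.1 ± 1.65 and 22.9 ± 1.92 FPKM (limma adjusted p = 0.262), and MYC at 115.1 ± 4.14 and 116.2 ± 3.92 FPKM (limma adjusted p = 0.914). The exact permutation test gave p = 0.1 for WTAP, the smallest that 3 against 3 libraries allow, and 0.9 for KDM4B. Within the pair of libraries with high mitochondrial mRNA the log2 difference was -0.67 for WTAP and -0.20 for KDM4B, and among the other 4 libraries it was -0.81 and 0.13. For KDM4B the sign turned without control 1 (-0.01), shWTAP 2 (-0.01) or shWTAP 3 (-0.06), in no case past the threshold, and METTL3 and HIF1A each passed the threshold in 1 alternative (lowest adjusted p = 0.0270 and 0.0469).

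**Figure D1:**
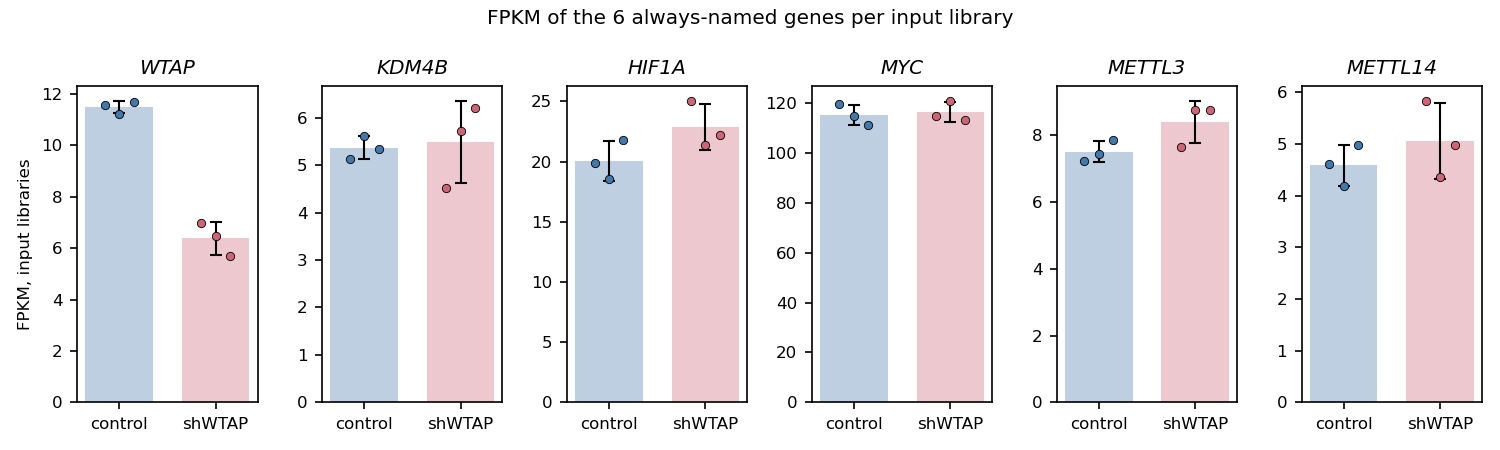
FPKM of WTAP, KDM4B, HIF1A, MYC, METTL3 and METTL14 in the 6 input libraries, with points for libraries, bars for group means and error bars for the SD of 3 libraries. WTAP lay between 5.69 and 6.97 FPKM in the shWTAP libraries and between 11.2 and 11.7 FPKM in the controls.

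The comparison across all tested genes called 443 of 11383 genes, 168 higher and 275 lower in shWTAP. CEACAM6, a surface glycoprotein of the granulocyte lineage, rose from 23.1 ± 0.753 to 62.7 ± 4.92 FPKM (2.72-fold, limma adjusted p = 0.000455), and BPI, a bactericidal protein of neutrophil granules, rose from 3.75 ± 0.172 to 10.3 ± 1.18 FPKM (2.76-fold, limma adjusted p = 0.00225). The surface glycoprotein CD52 and the calcium-binding protein S100A4 rose by 1.04 each on the log2 scale (SE 0.17 and 0.12), and the arrestin-related ARRDC3 by 0.96 (SE 0.11). MSMO1 of the sterol pathway, ST6GALNAC6, the actin-nucleating subunit ARPC1A and C19orf38 also rose, by 0.81 to 0.93. MYDGF, a secreted growth factor, fell from 31.0 ± 1.79 to 9.11 ± 0.936 FPKM, a log2 change of -1.66 (SE 0.09, limma adjusted p = 0.000455), and the kinase NEK7 changed by -1.37 (SE 0.12). BECN1, a core protein of autophagy, fell from 9.73 ± 0.213 to 4.07 ± 0.411 FPKM, JMJD8 and PHACTR4 changed by -1.05 and -1.02, and GYS1, muscle-type glycogen synthase, changed by -1.01 (SE 0.06). Of the 443 genes, 136 changed by 1.5-fold or more on the log2(FPKM + 1) scale, 45 higher and 91 lower. The groups did not overlap for 3211 tested genes (28.2%, where 10% is the share chance gives), and 2671 genes had an unadjusted p under 0.05.

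The number of calls varied with the libraries used. Without control 1, 2 or 3 the fit called 51, 58 and 61 genes, and without shWTAP 2 or 3 it called 81 and 46. Without shWTAP 1 it called 2751, without both libraries of high mitochondrial mRNA 3142, and with those 2 libraries as a block 1938, each including all 443. Under quantile normalization 327 genes were higher and 345 lower, and under median centring 323 and 339, so the excess of lower genes seen with FPKM as deposited (168 against 275) was small under both. CEACAM6, BPI, NEK7 and GYS1 stayed past the threshold in all 16 alternatives and MYDGF and BECN1 in all 15 that tested them. CD52, ST6GALNAC6 and C19orf38 lost their calls without any of the 3 controls, shWTAP 2 or shWTAP 3. MSMO1 lost its call without control 1, control 2, shWTAP 2 or shWTAP 3, ARPC1A and JMJD8 without control 1, control 2 or shWTAP 3, and PHACTR4 without any control or shWTAP 3. S100A4 lost its call without control 1 or control 3, and ARRDC3 without shWTAP 3. Within the pair of high mitochondrial mRNA and among the other 4 libraries, the log2 changes were 1.23 and 1.49 for CEACAM6, 1.03 and 1.36 for BPI, -1.49 and -1.75 for MYDGF, and -1.26 and -1.43 for NEK7.

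**Figure D2:**
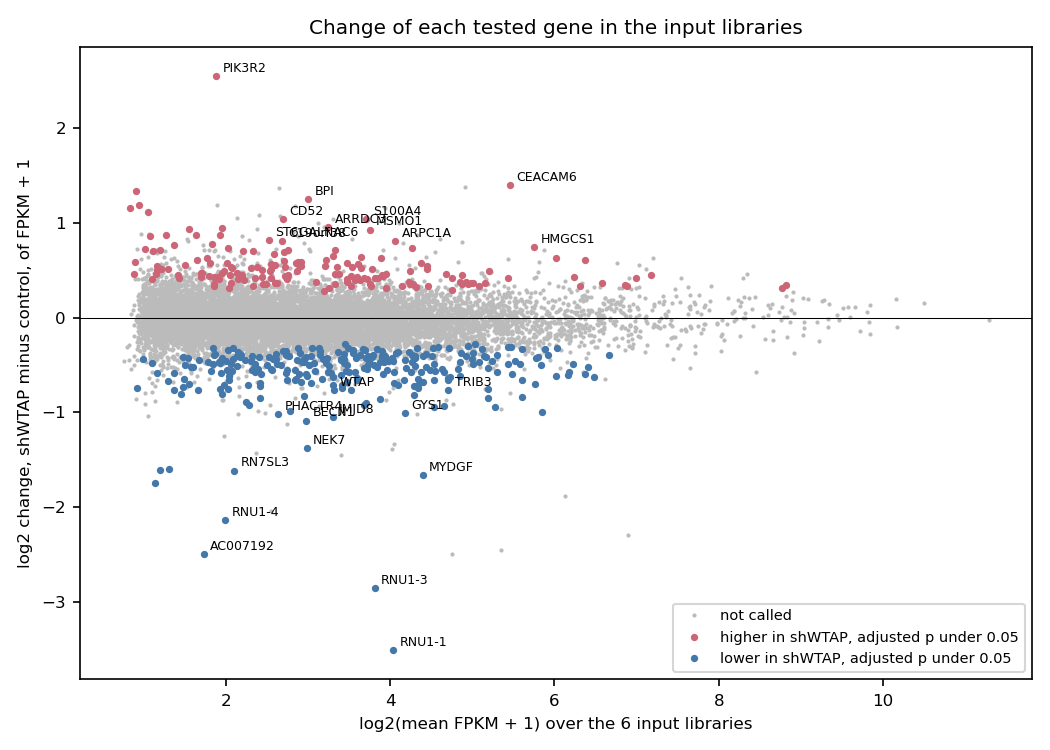
Log2 change of FPKM + 1 (shWTAP minus control) against log2 of the mean FPKM + 1 over the 6 input libraries, with 1 point for each of 11383 genes. The 168 genes called higher are red and the 275 called lower are blue. Under quantile normalization the split was 327 higher and 345 lower.

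Genes that share sequence or position with others held the largest changes. PIK3R2, a regulatory subunit of phosphoinositide 3-kinase (chromosome 19, 18153163 to 18170532, plus strand), was listed at 0.0600 to 0.0840 FPKM in the controls and 4.67 to 5.76 FPKM in shWTAP, a log2 change of 2.56 (SE 0.09, limma adjusted p = 4.7e-05). AC007192, a listed gene that spans PIK3R2 and IFI30 on the same strand, was at 4.52 to 4.85 FPKM in the controls and was listed at 0 in all 3 shWTAP libraries. IFI30 was called higher, at 0.0594 ± 0.0123 and 1.68 ± 0.245 FPKM. AC007192 and IFI30 were chosen after their values were seen. The summed FPKM of PIK3R2 and AC007192 was 4.71 ± 0.185 in control and 5.32 ± 0.577 in shWTAP, a log2 ratio of 0.17 (SE 0.10), so the values of the 2 genes are uncertain where counting could move fragments between them. Among the 443 genes, 110 overlapped another listed gene on the same strand (24.8%, against 31.6% of tested genes not called). They include S100A4, ST6GALNAC6, ARPC1A, C19orf38, MYDGF, BECN1 and PHACTR4 named above. The called list members BNIP3L, SDHA, ODC1, HERPUD1, TXNRD1, CD22 and PRG2 named below are also among them. Whether counting moved fragments at these genes was not tested. The U1 small nuclear RNA genes RNU1-1, RNU1-3 and RNU1-4 changed by -3.51 (SE 0.64), -2.85 (SE 0.48) and -2.14 (SE 0.43), and RN7SL3, a signal recognition particle RNA, by -1.61 (SE 0.13, limma adjusted p = 0.00307). The U1 genes are near-identical copies and varied among the controls, RNU1-1 from 10.1 to 55.3 FPKM, and their calls were lost without any of the 3 controls, shWTAP 2 or shWTAP 3. These RNAs lack a poly(A) tail, and the libraries were made from poly(A) RNA.

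Among gene lists set for these cells, targets of hypoxia and HIF were higher in shWTAP. Of 20 measured members, 2 rose, 0 fell and 18 did not pass, while 10 rose when adjusted over the list alone. BNIP3L, a mitophagy receptor, rose from 15.6 ± 1.91 to 23.8 ± 1.20 FPKM (limma adjusted p = 0.0236), and NDRG1 from 2.26 ± 0.156 to 3.59 ± 0.470 FPKM (limma adjusted p = 0.0402). The list median was 0.23 on the log2 scale against -0.03 for the other genes, and 18 of 20 members had a positive difference (camera adjusted p = 3.8e-07, and adjusted p = 0.833 with an estimated correlation). Cholesterol synthesis genes were also higher, with 3 of 20 members risen, 0 fallen and 17 not passed (7 risen when adjusted over the list alone). HMGCS1, which makes the precursor of mevalonate, rose from 39.4 ± 3.20 to 66.6 ± 1.44 FPKM (limma adjusted p = 0.00663), and MSMO1 stood at 8.36 ± 1.88 and 16.6 ± 0.776 FPKM. The median of this list was 0.19 (camera adjusted p = 7.7e-06, and adjusted p = 0.833 with an estimated correlation). Within the pair of high mitochondrial mRNA and among the other 4 libraries the list medians were 0.12 and 0.28 for hypoxia and 0.09 and 0.23 for cholesterol synthesis.

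Glycolysis genes had a median of 0.13, with 0 of 20 members past the threshold over all genes and 5 higher when adjusted over the list alone (camera adjusted p = 0.000529, and adjusted p = 0.833 with an estimated correlation). PFKP, a phosphofructokinase, was at 28.2 ± 1.40 and 34.5 ± 1.84 FPKM, and SLC2A3, a glucose transporter, at 12.7 ± 1.05 and 17.1 ± 1.52 FPKM. SLC2A3, ENO2, LDHA, SLC2A1, PGK1, ALDOC and HK2 are also on the hypoxia list. The calls on glycolysis and hypoxia are therefore not separate, and glycolysis without the shared genes was not tested. Cytosolic ribosomal protein genes had a median of 0.07, with 0 of 43 members past the threshold either way of adjusting (camera adjusted p = 0.0431, and adjusted p = 0.937 with an estimated correlation). RPS6 was at 433.7 ± 4.72 and 524.6 ± 34.5 FPKM, while RPS14 went the other way, at 236.0 ± 14.8 and 182.0 ± 21.7 FPKM. The call on ribosomal proteins was lost without control 3 (camera adjusted p = 0.764), without shWTAP 2 (0.384), without both libraries of high mitochondrial mRNA (0.434) and under quantile normalization (0.728) and median centring (0.0754), and it held in 8 of 17 alternatives. The glycolysis call was lost without overlapping genes (camera adjusted p = 0.208). Within the pair of high mitochondrial mRNA and among the other 4 libraries the medians were 0.08 and 0.17 for glycolysis and 0.10 and 0.04 for ribosomal proteins.

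Genes of ribosome biogenesis and targets of MYC were lower as a list, with a median of -0.15, 3 of 30 members with a positive difference, 2 fallen, 1 risen and 27 not passed, the same when adjusted over the list alone (camera adjusted p = 0.0200, and adjusted p = 0.937 with an estimated correlation). RRP9, a protein of the small nucleolar ribonucleoprotein that processes ribosomal RNA, fell from 21.5 ± 1.15 to 16.0 ± 0.376 FPKM (limma adjusted p = 0.0227), and FARSA, a subunit of phenylalanyl-tRNA synthetase, from 68.0 ± 1.83 to 51.6 ± 2.27 FPKM (limma adjusted p = 0.0221). ODC1, the first enzyme of polyamine synthesis, rose from 82.3 ± 2.64 to 107.0 ± 8.95 FPKM (limma adjusted p = 0.0454). Genes of the integrated stress response and unfolded protein response were lower as a list, with 3 of 21 members fallen, 0 risen and 18 not passed. Adjusted over the list alone, 4 fell. The median was -0.18, with a camera adjusted p of 0.0273 (adjusted p = 0.937 with an estimated correlation). A positive difference stood in 6 of the 21, among them HSPA5 (0.23), HSP90B1 (0.17) and PDIA4 (0.17), none past the threshold. TRIB3, a pseudokinase induced by ATF4, fell from 32.0 ± 1.22 to 18.4 ± 1.17 FPKM (limma adjusted p = 0.00518). HERPUD1, of endoplasmic reticulum protein degradation, and the transcription factor ATF3 fell by 0.51 (SE 0.08) and 0.38 (SE 0.07) on the log2 scale. The ribosome biogenesis call was lost without control 1 (camera adjusted p = 0.0987) or shWTAP 3 (0.0827), and both calls with the filter at 5 FPKM (0.0971 and 0.430). The stress call was also lost without shWTAP 1 (camera adjusted p = 0.0657), with the 2-level block for the libraries of high mitochondrial mRNA (0.0656), without both of them (0.111) and without overlapping genes (0.0925). It held in 11 of 17 alternatives, and the ribosome biogenesis call in 13. Within the pair of high mitochondrial mRNA and among the other 4 libraries the medians were -0.04 and -0.21 for ribosome biogenesis and -0.11 and -0.18 for the stress response. Of the 22 lists tested, camera called these 6, none held with an estimated correlation, and fry called 0 in a single direction after adjustment (lowest adjusted p = 0.107, for cholesterol synthesis). By the mixed p of fry, for change in either direction, 17 of 22 were called, with the lowest adjusted p of 0.000133 for inflammatory and immediate early genes, and this p does not set a list against other genes.

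**Figure D3:**
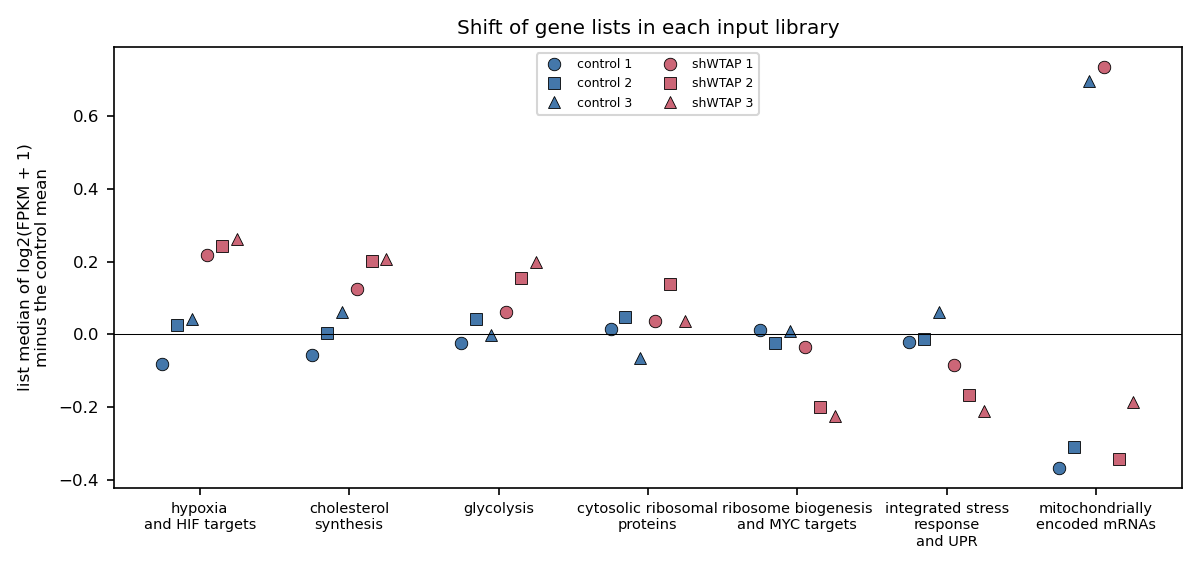
Median of log2(FPKM + 1) minus the control mean over the members of each list, with 1 point per input library, blue for control and red for shWTAP. For hypoxia and HIF targets the shWTAP libraries lay at 0.22 to 0.26 and the controls at -0.08 to 0.04, and for mitochondrially encoded mRNAs control 3 (0.70) and shWTAP 1 (0.74) lay apart from the other 4 libraries.

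The other 16 tested lists were not called by camera, and single members changed. In the m6A writer complex WTAP and RBM15, an RNA-binding subunit, fell (RBM15 from 6.78 ± 0.305 to 4.87 ± 0.443 FPKM, limma adjusted p = 0.0397), 0 of 8 rose over all genes and 6 did not pass (camera adjusted p = 0.762). Among erasers and readers of m6A 0 of 15 passed (camera adjusted p = 0.691). Of 19 lysine demethylases KDM4A fell, from 16.0 ± 0.516 to 11.3 ± 0.830 FPKM (limma adjusted p = 0.0208), and 18 did not pass (camera adjusted p = 0.727). In the list of ferroptosis and glutathione 2 of 19 members fell, the thioredoxin reductase TXNRD1 by 0.72 (SE 0.09) and the lipid peroxidase GPX4 by 0.52 (SE 0.09), and 17 did not pass (camera adjusted p = 0.684). Of 22 leukaemic stem and progenitor genes SMIM24 rose by 0.49 (SE 0.08), the transcription factor FLI1 fell by 0.38 (SE 0.06), LMO2 fell by 0.30 (SE 0.06), and 19 did not pass (camera adjusted p = 0.795). Of 20 myeloid differentiation genes CEBPE, a regulator of granulocyte maturation, rose by 0.55 (SE 0.10), and 19 did not pass (camera adjusted p = 0.815). Of 17 interferon-stimulated genes IFI6 rose by 0.49 (SE 0.07) and 16 did not pass, with IFIT1 at 1.97 ± 0.229 and 1.19 ± 0.158 FPKM (camera adjusted p = 0.405). RRM1, of deoxynucleotide synthesis, fell by 0.41 (SE 0.08) among 36 genes of S phase (camera adjusted p = 0.162), SDHA of respiratory complex II by 0.37 (SE 0.07) among 29 of oxidative phosphorylation (camera adjusted p = 0.888), and ATF3 among 12 immediate early genes (camera adjusted p = 0.795). Adjusted over the list alone, 2 interferon-stimulated genes rose and 5 fell, 3 genes of ferroptosis and glutathione fell, 3 stem and progenitor genes fell and 1 rose, 1 myeloid gene rose and 1 fell, 1 writer gene rose and 2 fell, and 1 reader, 1 demethylase, 1 gene of S phase, 1 of oxidative phosphorylation and 1 immediate early gene fell.

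No member passed among 34 genes of mitosis (camera adjusted p = 0.795), 16 targets of p53 (0.727), 21 apoptosis regulators (0.727), 9 inflammatory genes (0.727), 29 splicing factors (0.762) or 13 mitochondrially encoded mRNAs (0.727). Adjusted over the list alone, 2 targets of p53 rose and 1 fell, 1 inflammatory gene fell, and 0 passed in the other 4 of these lists. Without control 3 the mitochondrial list was called (camera adjusted p = 0.0183, median 0.47 above the other genes). Median, mean and camera differed in sign for p53 targets (-0.01, 0.01 and up), immediate early genes (0.00, -0.03 and down) and stem and progenitor genes (0.03, -0.00 and up). Of the 24 called list members that were not among the 20 largest changes, WTAP, HMGCS1 and TRIB3 kept their calls whichever library was left out. The other 21 lost them without control 1, control 2, control 3 or shWTAP 3, as did 20 of them without shWTAP 2, where CD22 kept its call. None lost its call without shWTAP 1.

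Markers of other cell types were mostly below the filter, and those lists were too short to test. Of the 32 replication-dependent histone genes only H2BC12 was measured, at 2.19 ± 0.829 and 0.948 ± 0.234 FPKM (limma adjusted p = 0.0910). The B cell marker CD22 rose from 0.529 ± 0.110 to 1.52 ± 0.117 FPKM (limma adjusted p = 0.0134), with 3 other B cell markers not passed. PRG2, an eosinophil granule protein on the list of mast cells and basophils, rose from 14.8 ± 1.53 to 21.2 ± 1.55 FPKM (limma adjusted p = 0.0392). CD3D, a T cell marker, was at 50.2 ± 1.48 and 53.1 ± 6.37 FPKM, EPCAM, an epithelial marker, at 41.5 ± 1.27 and 42.5 ± 6.67 FPKM, and the platelet-list gene NRGN at 13.2 ± 1.13 and 14.6 ± 2.30 FPKM, none past the threshold. The only erythroid marker at 1 FPKM or more was EPOR, at 1.89 ± 0.139 and 2.30 ± 0.680 FPKM.

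The peak lists addressed where m6A was found with and without the knockdown. They held 35341 peaks for control and 35851 for shWTAP, with no replicate of a peak. Of the control peaks 82.6% (95% Wilson interval 82.2% to 83.0%) overlapped an shWTAP peak by at least 1 bp, and 82.8% (82.4% to 83.2%) of the shWTAP peaks overlapped a control peak. The share fell by definition to 69.4% where at least 50% of the control peak had to be covered and to 47.9% where that had to hold both ways, and 94.1% of control peaks had an shWTAP peak in the same gene. Peaks without an overlap were weaker and shorter, with a median fold enrichment given by the authors of 4.51 against 6.77 in control and 4.34 against 7.06 in shWTAP, and a median exonic width of 181 nt against 508 nt and 151 nt against 449 nt. By annotation 46.8% of control peaks and 46.3% of shWTAP peaks lay in a 3' UTR, 34.3% and 35.3% in an exon and 18.9% and 18.5% in a 5' UTR. Control peaks covered 21.6 Mb of exonic sequence and shWTAP peaks 18.0 Mb once merged, of which 15.1 Mb was shared. Before merging, the sums were 23.1 Mb and 19.5 Mb, so some peaks of a list overlap each other and the peak counts are not counts of separate sites. The median width was 421 nt in control and 361 nt in shWTAP. These numbers come from separately called lists of unknown depth and carry no test.

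**Figure D4:**
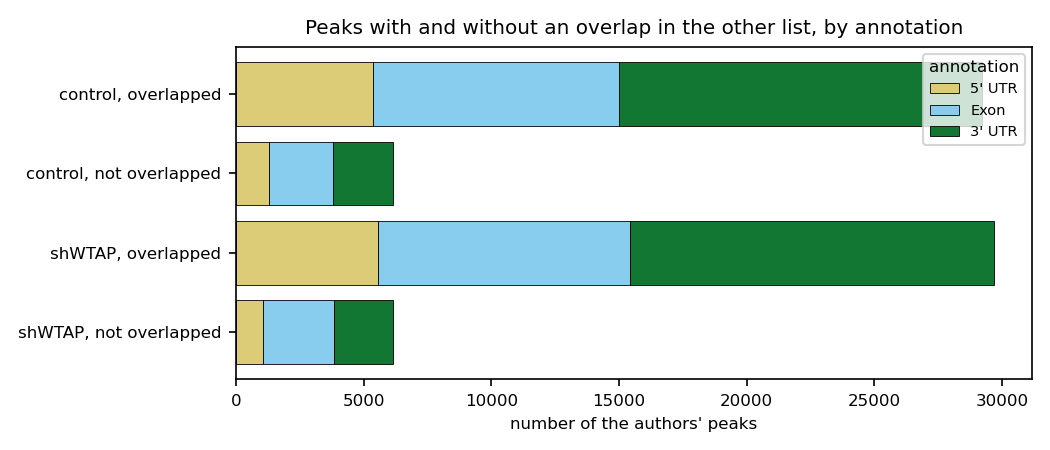
Number of the authors' peaks with and without an overlap in the other list, by annotation, with 1 bar per list and class. The overlapped peaks numbered 29192 in control and 29684 in shWTAP, and those without an overlap 6149 and 6167.

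KDM4B had 11 peaks in the control list and 10 in the shWTAP list. Of the control peaks 8 overlapped an shWTAP peak, and all 10 shWTAP peaks overlapped a control peak. The 3 without an overlap were a peak annotated as 5' UTR (chromosome 19, 4969113 to 4969173, 2.88-fold) and a pair annotated as 3' UTR (5153178 to 5153238 at 1.41-fold, and 5153448 to 5153538 at 1.32-fold), each 91 exonic nt or less. The control peak at 5140374 to 5141453, annotated as 3' UTR, had a fold enrichment of 33.8 within its list, and the shWTAP peaks there, 5140344 to 5140584 and 5140734 to 5141453, had 3.30 and 4.10 within theirs. Their log10 p was -8.62 in control and -4.16 and -3.26 in shWTAP, against -58.6 for the control peak at 5150406 to 5151859 (7.32-fold). Other sites on the gene lay either way. The peaks starting at 5112032 had 5.51 in control and 10.6 in shWTAP, and the shWTAP peak at 5151380 to 5151829, within the 7.32-fold control peak, had 3.86. Fold values are not compared between the lists, so no loss or gain at these sites can be read from them. The peak at 4960958 to 4962004 (21.0-fold in control) was assigned to KDM4B but lay outside its span of 4969113 to 5153598 and inside the span of UHRF1, 4903080 to 4962154. WTAP, METTL3 and METTL14 had 1 peak and HIF1A 2 peaks in each list, all overlapped. MYC had 4 peaks in control and 6 in shWTAP, but peaks within each list overlapped one another, so these are not counts of separate sites. The control peak at 127736033 to 127737629 was listed in shWTAP as 127736033 to 127736333 and 127736393 to 127737629. The shWTAP peak without an overlap was annotated as 3' UTR (chromosome 8, 127742861 to 127742951, 4.34-fold, log10 p of -1.43). Positions are as the authors' lists give them, counted from 1, on a build not given in the sources used here.

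**Figure D5:**
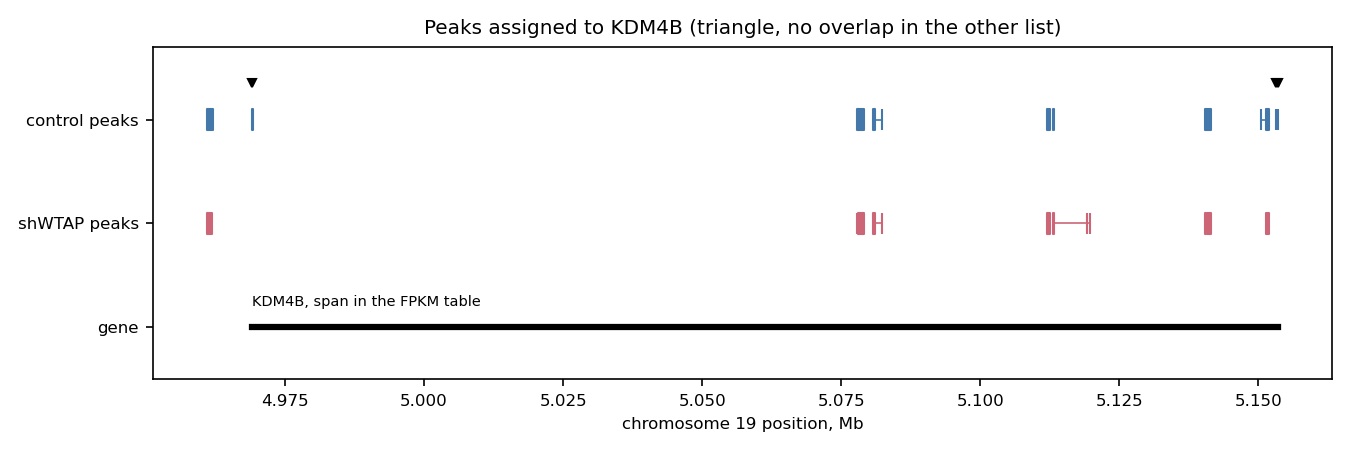
Positions on chromosome 19 in Mb of the peaks assigned to KDM4B in the control list (blue) and the shWTAP list (red), with boxes for exonic blocks, lines for the span of a peak and a black bar for the gene. Triangles mark the 3 control peaks with no overlap in the shWTAP list, and the peak at the left end lies outside the gene's span.

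The highest fold enrichments without an overlap in the other list belonged in control to NOMO3 (chromosome 16, 16232528 to 16232768, 5' UTR, 104.0), AL359258 (93.6), Y_RNA, TFG (44.0) and MED18 (39.8). In shWTAP they belonged to AC106782 (117.0 and 115.0 for 2 peaks), XAGE1B (86.8) and SULT1A3 (64.6 for 2 peaks). The spans of the 2 AC106782 peaks overlap each other, as do those of the 2 SULT1A3 peaks, so these are not separate sites. The peaks of AC106782 and SULT1A3 lie next to one another on chromosome 16. NOMO3, SULT1A3 and XAGE1B have near-identical copies, so the placing of their fragments is uncertain. Among overlapped peaks the highest were those of ADAMTS7 (791.0), CAPNS1 (749.0), FBXW4, SENP3 and GNB1 in control and of DHX36 (935.0), SENP3, GNB1, CRACD and MIR6836 in shWTAP.

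The last comparison asked whether RNA levels moved with the peaks of a gene. Among tested genes 8282 had a peak in both lists, 506 only in the control list, 496 only in the shWTAP list and 2099 in neither. Over all genes of the peak lists, 483 of 1812 control-only and 538 of 1970 shWTAP-only genes had a peak overlapped by a peak assigned to another gene in the other list, so these classes partly follow gene assignment. Genes with control-only peaks had a median log2 change of -0.02 against -0.03 for the other genes with a peak (camera adjusted p = 0.689, and adjusted p = 0.878 with an estimated correlation), and 23 of them were called (4.54%, against 3.85%). Genes with shWTAP-only peaks had a median of -0.04 against -0.03 (camera adjusted p = 0.689), and 24 were called (4.84%). Genes with peaks in both lists had a median of -0.03 against -0.01 for genes with none (camera adjusted p = 0.689), and 314 were called (3.79%, against 3.91%). In 1000 draws of peak-marked genes matched on mean expression to the unmarked ones the median was -0.03. Peaks in both lists were assigned to 19 of 20 cholesterol, 15 of 20 hypoxia, 16 of 20 glycolysis, 24 of 30 ribosome biogenesis, 18 of 21 stress response and 16 of 43 ribosomal protein genes, and these shares were not tested. CEACAM6, CD52, S100A4, ARRDC3, MSMO1, MYDGF, NEK7, JMJD8 and GYS1 had peaks in both lists, ST6GALNAC6 and PHACTR4 in the shWTAP list only, and BPI, ARPC1A, C19orf38 and BECN1 in neither.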

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

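The fits without both libraries of high mitochondrial mRNA, with a 2-level block for them and without overlapping genes, the false discovery rate filter, the overlaps by whole span and by same strand, the classes of genes whose peaks all lack an overlap, and the reading of list directions from camera were chosen after results were seen. WTAP stayed lower and past the threshold in all 16 alternatives (log2 change -0.84 to -0.69, adjusted p 0.00171 to 0.0498). Against 443 changed genes (168 higher, 275 lower), the fit without the filter called 82 (31 and 51), where all genes of the table entered the adjustment, quantile normalization 672 (327 higher), median centring 662 (323 higher), the fit without both libraries of high mitochondrial mRNA 3142 (1323 and 1819) and the 2-level block 1938 (724 and 1214). Leaving out 1 library gave 46 to 2751 changed genes, 19 to 1031 higher and 27 to 1720 lower, with 46 to 81 for any of the 5 libraries other than shWTAP 1. With the replicate block the fit called 77 genes (33 and 44), at fewer degrees of freedom. Deviations of same-numbered libraries correlated at -0.11, 0.17 and -0.14. Each control correlated best with an shWTAP library of another number, though control 2 did so narrowly (0.174 with shWTAP 3, 0.167 with shWTAP 2). With 3 libraries per group these deviations cannot tell whether the numbers pair the libraries, and the block rests on shared numbers alone. The number of lists called was 6, and it was 3 without overlapping genes, 0 with an estimated correlation and 4 to 7 in the other alternatives. KDM4B ranged from -0.0630 to 0.13 when 1 library was left out. The direction of a list or peak class is that of camera and the value is its median over the median of other genes, so a direction can turn without a change of sign. The input change of genes with shWTAP-only peaks was -0.0165, and the direction turned with the filter at 5 FPKM (-0.00642), without overlapping genes (-0.00541), with the 50% of each list with the smallest p (0.0110) and with the false discovery rate filter (-0.0126). No alternative passed the threshold for any of the 3 peak classes (adjusted p 0.439 to 0.990). Keeping the 50% with the smallest p left 17670 control and 17925 shWTAP peaks by construction. The overlapped share of 82.6% became 91.8% there, 80.1% among peaks of at least 4-fold, 86.5% under the false discovery rate filter, 69.4% with 50% of the control peak covered, 47.9% with 50% covered both ways, 83.7% by whole spans, 80.5% by same strand and 94.1% by gene. Directions also turned for lists not called in the reported fit. At the 5 FPKM filter these were the list oxidative phosphorylation (0.0395), the list mitosis and G2/M (0.0198), the list p53 targets (-0.0133), the list interferon-stimulated genes (0.0268) and the list immediate early genes (0.0962). Under quantile normalization they were oxidative phosphorylation (0.0214), mitosis (0.00516) and the list splicing factors (-0.0382), under median centring oxidative phosphorylation (0.0231), and without both libraries of high mitochondrial mRNA immediate early genes (0.0577). When 1 library was left out, the ranges of lists that turned were -0.0110 to 0.0597 for oxidative phosphorylation, -0.20 to 0.47 for mitochondrially encoded mRNAs, -0.0481 to 0.0276 for mitosis, -0.0313 to 0.0826 for myeloid differentiation, -0.0269 to 0.0618 for immediate early genes and -0.0839 to -0.0171 for splicing factors. The log2 ranges of genes that turned, none of them called in the reported fit, were -0.0137 to 0.0400 for MYC, -0.0353 to 0.51 for MT-ND1, -0.16 to 0.47 for MT-ND6, -0.62 to 0.0880 for MT-CO1, -0.0213 to 0.13 for CD3D, -0.11 to 0.0742 for CD4, -0.00758 to 0.14 for PAX5 and -0.0981 to 0.0872 for EPCAM. With all libraries or without the 2 of high mitochondrial mRNA, the gene CD4 turned under quantile normalization (0.0210), under median centring (0.00782) and without those 2 (0.0838), as did the gene MYC (-0.00267), the gene CD3D (-0.0393) and the gene EPCAM (-0.0738) in that last fit. Of the values of single genes and lists over all alternatives, 1780 stayed on their side of the threshold, 239 lost a call, 188 gained a call and 43 turned. Where no cause is named it was not tested. Genes below a filter or overlapping another gene had no value in those fits, the test of IP over input and its alternatives were not run, and depth, which is unknown, limits what low genes can show.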

Other observations

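The KEGG test, all tests of the 3 patterns and of the hypoxia list below, and the splits of the libraries were chosen after the results they bear on were seen.

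Single genes of cell adhesion and of the blood cell surface were called, some higher and some lower. HLA-DPA1, a class II antigen presentation gene, rose from 1.19 ± 0.0753 to 3.02 ± 0.108 FPKM (SD, n = 3, limma adjusted p = 0.00370), ICAM3 from 13.4 ± 1.12 to 23.0 ± 1.11 FPKM (limma adjusted p = 0.00687), CD24 from 3.98 ± 0.315 to 7.05 ± 0.328 FPKM (limma adjusted p = 0.00687), and the integrin subunit ITGA4 by 0.36 (SE 0.08). The hyaluronan receptor CD44 fell from 66.2 ± 1.56 to 40.5 ± 5.35 FPKM (limma adjusted p = 0.0146), and the integrin subunit ITGB1 from 61.4 ± 3.29 to 34.1 ± 4.85 FPKM (limma adjusted p = 0.0116). Of 286 KEGG pathways with at least 10 measured members, camera called 6, all higher in shWTAP, among them cell adhesion molecules (5 of 40 genes risen, 1 fallen, adjusted p = 0.00194), hematopoietic cell lineage (5 of 28 risen, 1 fallen, adjusted p = 0.00194) and steroid biosynthesis (2 of 16 risen, adjusted p = 0.00763). The others were type I diabetes mellitus (HLA-DPA1 and HLA-B risen of 10, adjusted p = 0.00763), other glycan degradation (2 of 16, adjusted p = 0.0390) and glycosaminoglycan degradation (IDS, GLB1, HPSE and HYAL3 risen of 14, adjusted p = 0.0404). With an estimated correlation 0 pathways were called. The real split called 6 pathways and the highest other split 9, with 2 of 10 splits at 6 or more, and splits of 3 against 3 are too few for a share under 0.05.

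Of 43 genes of aminoacyl-tRNA biosynthesis 5 fell and 0 rose. WARS1, tryptophanyl-tRNA synthetase, fell from 32.1 ± 0.760 to 16.4 ± 2.40 FPKM (limma adjusted p = 0.00687), and AARS1, MARS1, SARS1 and FARSA fell by 0.37, 0.33, 0.47 and 0.39 on the log2 scale. The pathway as a set was not called (camera adjusted p = 0.552, and adjusted p = 1 with an estimated correlation).

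PIK3R2 was higher in shWTAP while AC007192, whose span covers it, was listed at 0 there. A rise of at least 2-fold in RNA over PIK3R2 is argued against by the summed FPKM of both genes, whose log2 ratio was 0.17 and with 2 SE added 0.37, though the sum is approximate because the lengths behind each FPKM are unknown. Fragments moved between overlapping gene models by the authors' counting may account for the pair, since the sum stayed near level. A switch from joined to separate transcripts in the cells stays open: 5 other genes with joined names went from 0 to 5 FPKM or more within a group, BLOC1S5-TXNDC5 at 51.8 in control 1 and 0 in the other 5 libraries, so such jumps occur without the knockdown, yet here all 3 libraries of each group are alike. No read-level data were analysed here to separate these.

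shWTAP 1 lay between the controls and the other shWTAP libraries, and without it 2751 genes were called. Control cells mixed into shWTAP 1 would give each gene 1 share of the change, but over 85 genes changed at least 2-fold without it the share had an interquartile range of 0.802, with 49 genes under 0.25 and 19 over 0.75, against an expected noise SD of 0.135. A proportionally weaker knockdown is argued against by WTAP itself, where shWTAP 1 showed 0.837 of the fall of the other shWTAP libraries, against a median share of 0.128 over the 85 genes and 0.312 over all 2751 on the log2 scale, both of them genes selected without shWTAP 1. A batch shared with control 3, the other library of high mitochondrial mRNA, as the whole cause is argued against by the shift of control 3 along the change, 0.0679 of that of shWTAP 1 (-0.09 to 0.17 over 4 choices of library), although their deviations correlated at 0.31, so a batch as part of the cause stays open. A difference in timing or state of that culture, or a mix of causes, was not tested.

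Some short RNAs without a poly(A) tail were lower in shWTAP: of 11 picked after their values were seen, with no set test, 9 were below every control in every shWTAP library, RNU4-2 and RPPH1 were not, and 5 of 8 tested were called. Against control 2 and control 3 alone, the median log2 ratio of these RNAs was -2.17 (-3.40 to -1.26). Because they were picked by their values, this only describes them. It cannot weigh whether control 1 alone carries a difference in such RNAs. More such RNA carried into the control libraries at poly(A) selection is a candidate explanation. Summed replication-dependent histone mRNA, which as a class also lacks the tail, had a log2 ratio of -0.73 (SE 0.21). It was at 6.18 to 7.66 FPKM in controls and 3.32 to 5.10 in shWTAP. H2BC12, the only one above the filter, held 2.19 of a mean of 6.70 FPKM in controls and 0.948 of 4.09 in shWTAP. It was not called (limma adjusted p = 0.0910), so 1 uncalled gene carries a large part of the fall and the sum is weak evidence. Fewer cells in S phase would lower histone mRNA too (the list of S phase genes had a median of -0.09 with 12 of 36 positive and a camera adjusted p of 0.162, and was called in 1 of 17 alternatives, without the filter, at 0.0238), and neither a true fall of the short RNAs nor a difference in fragment size between the libraries was tested.

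Splits of the 6 libraries into 3 against 3 number 10, too few for a share under 0.05. The real split called 443 genes (168 higher, 275 lower), the highest other 3. The sides of a mixed split have no order, so its larger direction was set against both counts, and the highest was 2 for either. Thus 1 of 10 splits, the real one, gave as many for each count. At an unadjusted p under 0.05 the real split had 2671 genes, control 1, control 3 and shWTAP 1 against the rest 1778, and control 1, shWTAP 2 and shWTAP 3 against the rest 1243, both with the pair of high mitochondrial mRNA on the same side. Splits that mix the groups hold any effect of the knockdown within each side, which widens their variance. For gene lists the real split called 6 and the highest other 10, and 4 of 10 splits gave 6 or more. The 3 others that did so place control 3 and shWTAP 1 on the same side, where the 5 mixed splits that part them gave at most 3, and the 2-level block for these libraries gave 5 lists. For the peak classes, by -log10 of the p of camera, the real split gave 0.162 for control-only peaks (highest other 0.468, 5 of 10 as large), 0.176 for shWTAP-only peaks (0.377, 3 of 10) and 0.470 for peaks in both lists (0.725, 4 of 10).

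The hypoxia list was looked at further and then not weighed. Its -log10 p by camera was 7.76 in the real split, and the highest of the others were 5.79, 5.41 and 5.10. Small camera p-values for this list thus also arose in splits that mix the groups. All 3 shWTAP libraries had 18 of 20 members above the control mean, against 0, 13 and 17 in control 1, 2 and 3. The 13 members not on the glycolysis list had a median log2 change of 0.24.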
